A study of Homo sapiens with 8 samples.

How the data were processed

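Primary human airway smooth muscle cells at passage 5 were cultured in medium with 10% serum and transduced with Ad-GFP or Ad-KLF15 at 50 infectious units per cell for about 17 hours, then kept for 4 hours in fresh medium, per the labels. RNA was sequenced on an Ion Proton instrument after library construction with a stranded mRNA kit from 100 ng of total RNA, per the labels' protocols. The deposited values were read counts per Ensembl gene, not normalized. GSNAP, HTSeq 0.6.0, DESeq2 1.4.5, R 3.1.0 and the hg19 build are named in the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes may not have been separated. A table of reads not counted in genes was used only for shares: 5.52% to 14.8% of reads per library fell in no annotated gene, 2.83% to 3.05% were ambiguous, and the classes for unaligned, low-quality and non-unique reads were 0 in every library.

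Symbols were taken from a table of gene names and matched 50156 of 56515 identifiers. The GENCODE release held here is on another build, so no coordinates are printed. It was used for gene types, transcript GC content and which genes neighbour each other.

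Libraries were compared in R 4.3.3. The main test was edgeR 4.0.16 on the counts as deposited, with filterByExpr (minimum count 10, minimum total 15), TMM factors and the quasi-likelihood test with group as the only term. Benjamini-Hochberg adjusted p under 0.05 was the threshold over 16670 tested genes, 367 of them without a symbol. Fold changes are Ad-KLF15 over Ad-GFP. The SE of a log2 fold change was taken from the spread of log2 CPM between libraries, with a prior count of 2. That prior count damps the spread at a few counts, so the SE can understate the error of genes near the floor. Values in CPM use TMM-scaled library sizes and are given as mean ± SD of 4 libraries. A gene with no counts in a group was set to a floor of 3 counts over the group, and intervals on count ratios cover counting error only. The common biological coefficient of variation was 8.89%.

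The 24 gene lists (596 genes, 591 matched) and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 23 lists, again with an estimated correlation, and with fry, which asks whether the members move one way and does not compare them with other genes. Named genes were KLF15; PLCD1, BCAT2 and PRODH; the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 2 and non-overlapping groups, leaving out features without an ordinary symbol, pseudogenes and sex-specific genes; up to 4 called members of each list by smallest p; and every called KLF or SP member. Some genes that these rules took are not reported here.

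The test was tried on simulated counts drawn from the real means and library sizes. Of 1.5-fold changes it found 71.4% of 49 raised and 61.2% of 49 lowered genes. For 2-fold changes the shares were 91.7% of 48 raised and 88.9% of 45 lowered genes. Over 15779 genes there were 20 false calls, 11.8% of the calls, a share above the adjusted p threshold. Far fewer genes were changed, about evenly in both directions, than the 11205 called in the real comparison. These rates therefore cannot be carried over to it, and the scaling was not tried under so many changes.

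The replicates of a group differed by more than sampling noise in every pair (chi-square per degree of freedom 3.45 to 17.9). None was therefore counted as a repeat run of another library. That comparison cannot tell separate cultures from separate libraries of the same culture. The first principal component held 85.2% of the variance and separated the groups. Alternatives were size factors of DESeq2 1.42.0, upper-quartile scaling, other count filters, a replicate block, a robust fit, KLF15 left out of library sizes, DESeq2, limma 3.58.1 with voom, a threshold of 0.01, and leaving out each library. Total-count scaling, removal of a GC trend fitted to each library and the use of Ad-GFP libraries 1 and 2 alone were chosen after seeing the data. The GC trend was fitted to each library's deviations from the mean of all libraries. Its removal therefore also takes out any true difference between the groups that follows GC content.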

Results

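Gene expression was measured by RNA sequencing in primary human airway smooth muscle cells, the contractile cells of the airway wall, grown in culture and transduced with an adenovirus. Of 8 libraries, 4 came from cells given a virus expressing green fluorescent protein (Ad-GFP, the control) and 4 from cells given a virus expressing KLF15 (Ad-KLF15), a zinc finger transcription factor of the Krüppel-like family. The comparison asked which transcripts respond to raised KLF15 in this cell type. Every library came from transduced cells, so a difference between the virus preparations would follow the groups and could not be told apart from KLF15. This limit holds for every gene and list below. The Ad-GFP libraries held 18597687, 17127002, 14289443 and 15329264 reads counted in genes, and the Ad-KLF15 libraries held 20394113, 16368031, 16750450 and 12733915. The labels describe the replicates as biological, without saying whether they came from separate donors, so the p-values measure the spread between these cultures. Reads in no annotated gene made up 12.1% ± 2.38 of the Ad-GFP libraries and 7.54% ± 2.23 of the Ad-KLF15 libraries (SD, n = 4 each, exact two-sided permutation test, p = 0.057).

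KLF15 itself (ENSG00000163884) separated the groups in every library. It was at 0.23 ± 0.04 CPM (counts per 1000000) in Ad-GFP and 5431 ± 332 CPM in Ad-KLF15 (SD, n = 4), a log2 fold change of 14.49 (SE 0.10, edgeR adjusted p = 1.66e-23). The Ad-GFP libraries held 16 KLF15 counts in all and the Ad-KLF15 libraries 333218. The exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 libraries can give. Across the transcriptome, 5784 genes were higher and 5421 lower in Ad-KLF15 among 16670 tested, and 5465 did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). With library totals alone as the scaling, which moved the median log2 fold change of all genes from -0.02 to -0.22, the split was 4625 higher and 7324 lower. At least 2-fold changes were more numerous upward: 2888 genes rose and 1537 fell by that much. At least 8-fold, the counts were 569 and 60. The libraries of the groups did not overlap for 10239 genes, 2.86% being the share chance gives for 4 against 4.

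PLCD1, a phospholipase C that cleaves membrane phosphoinositides, rose from 22.3 ± 1.29 to 855 ± 37.2 CPM (log2 fold change 5.26, SE 0.05, edgeR adjusted p = 8.01e-20). BCAT2, the mitochondrial enzyme that starts the breakdown of branched-chain amino acids, rose from 12.6 ± 2.28 to 150 ± 5.79 CPM (log2 fold change 3.56, SE 0.13, edgeR adjusted p = 1.82e-15). PRODH, which starts proline breakdown, had 1 count over the Ad-GFP libraries and 32 over the Ad-KLF15 libraries and fell below the count filter of the main test. These 3 genes were chosen from prior knowledge of KLF15.

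The largest rises were of genes nearly silent in the control. AZGP1, a secreted lipid-mobilizing protein, had no counts in Ad-GFP and 92.1 ± 2.59 CPM in Ad-KLF15, at least 2145-fold higher against a floor of 3 counts over the group. SLC39A2, a zinc transporter, also had no Ad-GFP counts and was at least 321-fold higher. KISS1R, the kisspeptin receptor, had 3 Ad-GFP counts and reached 159 ± 8.24 CPM, a ratio of 3718 (95% counting interval 1272 to 18031). Its log2 fold change was 11.62 with all libraries and 12.52 without Ad-GFP library 2. LAG3 (log2 fold change 9.11, SE 0.29, and 9.95 without Ad-GFP library 3), IZUMO4 (8.47, SE 0.38), COL9A3 (8.16, SE 0.24) and CDKN1C, an inhibitor of cyclin-dependent kinases (8.40, SE 0.50), rose from under 1 CPM. LAG3, IZUMO4 and COL9A3 had 5, 9 and 11 Ad-GFP counts, few enough for the SE to understate the error. SH2D3C, CPLX1 and CHST1, with 1, 3 and 2 Ad-GFP counts, completed the 10. Of the 10 genes with the largest falls, 5 encode inflammatory mediators: CXCL3 (-5.45, SE 0.84), IL1B (-5.21, SE 0.75), CXCL8 (-5.15, SE 0.84), CCL20 (-4.49, SE 0.90) and CXCL1 (-4.27, SE 0.92). Their size rests in part on Ad-GFP library 4, without which the log2 fold change was -4.47 for CXCL3, -4.30 for IL1B, -4.13 for CXCL8, -3.71 for CCL20 and -3.24 for CXCL1. Without Ad-KLF15 library 4 that of CCL20 was -5.68. The others were DPYSL5 (-5.68, SE 0.30), SLC16A6 (-4.83, SE 0.44), the tight junction gene CLDN1 (-4.79, SE 0.50), the growth factor gene EREG (-4.74, SE 0.33) and PEX5L (-4.33, SE 0.18). Each passed the edgeR test, with adjusted p between 2.42e-05 (CXCL1) and 3.68e-14 (DPYSL5).

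**Figure D1:**
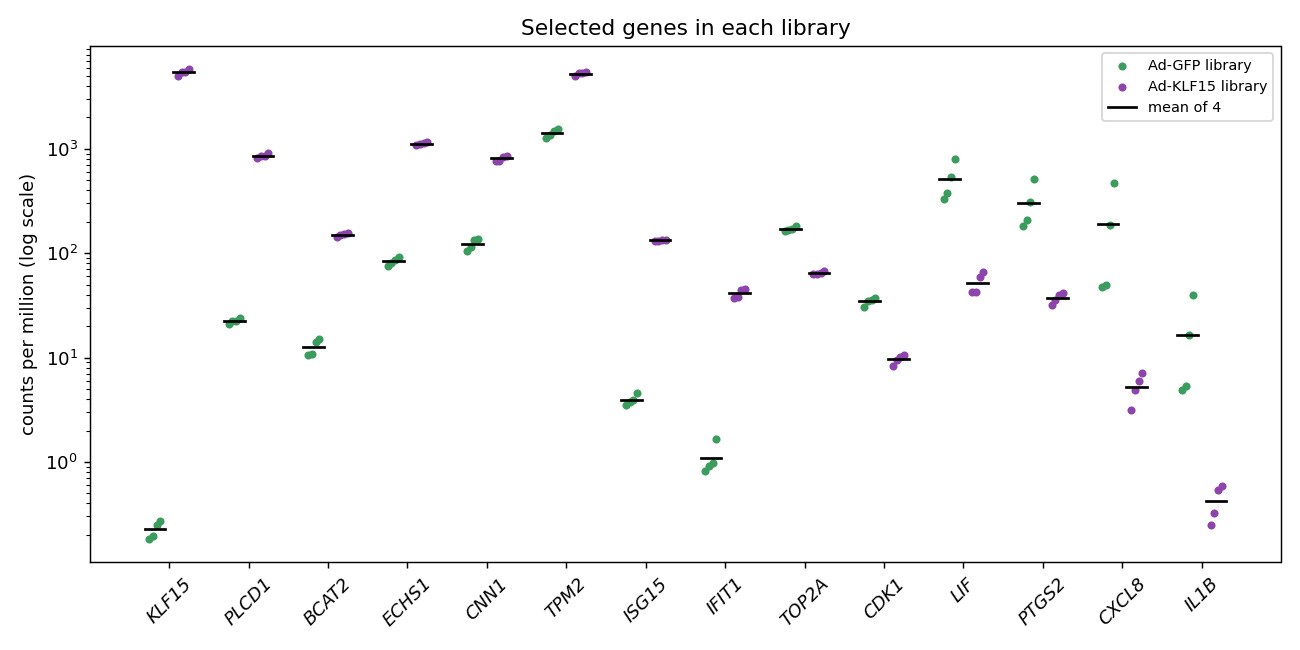
CPM on a log axis for 14 genes, with 1 point per library, Ad-GFP to the left and Ad-KLF15 to the right of each gene, and a bar at the mean of 4 libraries. KLF15 rose from a mean of 0.23 to 5431 CPM, ISG15 from 3.94 to 133 CPM, and the Ad-GFP libraries spread most widely for CXCL8 and IL1B.

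Genes of the NF-kB inflammatory response fell as a group. Of 26 tested members, 21 were lower, 2 higher and 3 did not pass, with a median log2 fold change of -3.03 (camera adjusted p = 0.00370, and adjusted p = 0.794 with an estimated correlation). LIF, a cytokine of the interleukin-6 family, fell from 513 ± 217 to 52.3 ± 11.9 CPM (log2 fold change -3.29, SE 0.34, edgeR adjusted p = 1.10e-09). The chemokine CCL2 (-3.04, SE 0.25) and the cyclooxygenase gene PTGS2 (-3.04, SE 0.34) fell by similar amounts. TNFAIP2 went the other way, from 25.8 ± 8.08 to 797 ± 17.5 CPM. The controls differed among themselves here: over the 21 members that fell, Ad-GFP library 4 lay a median of 1.41 log2 units above the other 3 controls, and Ad-GFP library 3 lay 0.77 above libraries 1 and 2. Ad-KLF15 library 4 lay 0.11 above the other 3 (SE 0.12 from a bootstrap over the 21 members, not over cultures). Against Ad-GFP libraries 1 and 2 alone, an alternative chosen after seeing the data, the same 21 members were lower and 4 were higher, with a median of -2.40 over the 26.

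Interferon-stimulated genes rose. Of 29 tested members, 27 were higher and 2 did not pass, with a median log2 fold change of 2.03 (camera adjusted p = 1.00e-13). This was the only list whose call held with an estimated correlation (adjusted p = 0.0407). With total-count scaling 26 members were higher and 1 lower, and with the GC trend removed 28 and 1. ISG15, a ubiquitin-like protein, rose from 3.94 ± 0.43 to 133 ± 0.999 CPM (log2 fold change 5.07, SE 0.07, edgeR adjusted p = 1.78e-18). The antiviral genes IFIT1 (5.21, SE 0.21) and IFIT3 (3.64, SE 0.11) and the transcription factor IRF1 (3.41, SE 0.11) also rose. Glucocorticoid-induced genes went both ways: of 24 tested, 6 were higher, 10 lower and 8 did not pass, and the list did not differ from other genes (camera adjusted p = 0.964). Its median was -0.05 and its mean 0.10. MAOA (3.20, SE 0.11) and KLF9 (1.96, SE 0.06) rose, while ANGPTL4 (-1.65, SE 0.15) and the metallothionein MT2A (-1.47, SE 0.16) fell.

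Smooth muscle contractile genes included 11 higher and 2 lower of 20 tested, and 7 that did not pass; with the GC trend removed the counts were 6 and 6. The list test missed its threshold (camera adjusted p = 0.067, and adjusted p = 0.820 with an estimated correlation), but passed with a replicate block (adjusted p = 0.019) and without Ad-GFP library 1, 2 or 4 (0.0301, 0.0228 and 0.0418). CNN1, which encodes calponin, rose from 122 ± 15.2 to 811 ± 46.1 CPM (log2 fold change 2.73, SE 0.10, edgeR adjusted p = 4.02e-15), and the tropomyosin TPM2 rose from 1419 ± 119 to 5268 ± 215 CPM (1.89, SE 0.07). The rises of PDLIM7 (1.01, SE 0.06) and the filamin FLNA (0.81, SE 0.05) turned to -0.01 and -0.07 with the GC trend removed, and neither passed. Of 18 hypertrophy and myocardin, SRF, MEF2 and GATA regulators, 9 were higher, 6 lower and 3 did not pass (camera adjusted p = 0.119), and 7 were higher and 7 lower with total-count scaling. NFATC4 (3.19, SE 0.07), NFATC1 (3.20, SE 0.13) and MEF2D (1.48, SE 0.09) rose, and the calcineurin regulator RCAN1 fell (-0.92, SE 0.07). Phospholipase C and Gq calcium signalling genes divided evenly, 12 higher, 12 lower and 6 not passing of 30 (camera adjusted p = 0.131). Besides PLCD1, PLCD3 (2.61, SE 0.05), PLCB3 (2.33, SE 0.03) and the calcium sensor STIM1 (1.97, SE 0.05) rose.

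Genes of branched-chain and other amino acid breakdown rose as a group: 20 of 27 were higher, 4 lower and 3 did not pass (median 0.48, camera adjusted p = 0.000558, and adjusted p = 0.361 with an estimated correlation). The split was 14 and 5 with total-count scaling and 17 and 4 with the GC trend removed. ALDH6A1 of valine breakdown (log2 fold change 3.87, SE 0.13), BCKDHB of the branched-chain ketoacid dehydrogenase (3.19, SE 0.05) and the glutamate dehydrogenase GLUD1 (1.81, SE 0.03) rose with BCAT2. In fatty acid uptake and oxidation, 20 of 28 were higher, 3 lower and 5 did not pass (median 0.54, camera adjusted p = 0.0224, and adjusted p = 0.411 with an estimated correlation), and with the GC trend removed 17 were higher and 6 lower. ECHS1, an enoyl-CoA hydratase, rose from 83.5 ± 6.91 to 1123 ± 33.1 CPM (3.75, SE 0.06, edgeR adjusted p = 3.34e-18). PPARA (1.34, SE 0.04), CPT1A, which admits fatty acids to mitochondria (1.30, SE 0.06), and ETFA (0.89, SE 0.02) rose less. Cholesterol synthesis genes were higher for 12 of 24, lower for 4 and did not pass for 8 (median 0.32, camera adjusted p = 0.0139, and adjusted p = 0.587 with an estimated correlation), and the split was 10 and 7 with total-count scaling and 11 and 7 with the GC trend removed. TM7SF2 (3.97, SE 0.14), LSS (3.17, SE 0.03), ACAT2 (2.39, SE 0.07) and FDFT1 (2.01, SE 0.07) led them. Glycolysis and hypoxia genes went both ways, with 13 higher, 11 lower and 6 not passing of 30 (camera adjusted p = 0.853), a split that turned to 11 and 14 with total-count scaling and 11 and 17 with the GC trend removed. The median was 0.09 and the mean 0.23, while the direction given by camera, in a test that did not pass, was downward. The glucose transporter SLC2A4 rose from 0.73 ± 0.50 to 22.4 ± 3.31 CPM (4.95, SE 0.47), ENO2 (1.82, SE 0.13) and TPI1 (0.98, SE 0.06) rose, and LDHA, which makes lactate, fell (-1.32, SE 0.04).

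Cell cycle and DNA replication genes fell. Of 37 tested, 33 were lower, 3 higher and 1 did not pass, with a median of -1.08 (camera adjusted p = 1.02e-09, and adjusted p = 0.361 with an estimated correlation). The kinase genes CDK1 (log2 fold change -1.83, SE 0.10) and AURKA (-1.55, SE 0.07), the replication licensing gene MCM3 (-1.41, SE 0.07) and the topoisomerase TOP2A (-1.39, SE 0.04) fell. TOP2A went from 171 ± 7.95 to 64.9 ± 1.81 CPM (edgeR adjusted p = 2.09e-13). Among p53 target genes 13 were higher, 10 lower and 3 did not pass of 26 (camera adjusted p = 0.285), and with the GC trend removed the split was 11 and 13. BBC3 (2.79, SE 0.08), GDF15 (2.73, SE 0.12), RRM2B (2.01, SE 0.05) and SESN1 (1.81, SE 0.07) rose. Of 29 ATF4 and unfolded protein response genes, 7 were higher, 16 lower and 6 did not pass (camera adjusted p = 0.340). DDIT3 (3.01, SE 0.09) and the serine synthesis gene PHGDH (1.10, SE 0.06) rose, while the amino acid transporter SLC7A5 (-1.95, SE 0.22) and PSAT1 (-0.75, SE 0.08) fell. Heat shock genes had 8 higher, 10 lower and 1 not passing of 19 (camera adjusted p = 0.732). Their median was -0.21 and their mean 0.24, and the direction given by camera, in a test that did not pass, was upward. CRYAB rose (2.74, SE 0.17), as did DNAJB1 (1.31, SE 0.05) and the near-identical copies HSPA1A (2.65, SE 0.09) and HSPA1B (1.71, SE 0.04), between which reads cannot be divided with certainty.

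Immediate-early genes had 6 higher, 13 lower and 4 not passing of 23 (median -0.32, camera adjusted p = 0.266). JUND rose (log2 fold change 2.74, SE 0.04), and SPRY2 (-1.61, SE 0.09), MYC (-1.54, SE 0.07) and FOSL1 (-1.09, SE 0.05) fell. Circadian clock genes had 10 higher, 8 lower and 1 not passing of 19 (camera adjusted p = 0.075). DBP rose from 0.95 ± 0.22 to 44.5 ± 3.92 CPM (5.51, SE 0.16), and PER3 (2.67, SE 0.03), NR1D1 (2.53, SE 0.24) and TEF (2.36, SE 0.10) rose. Of 18 other KLF and SP family members, 13 were higher, 2 lower and 3 did not pass (median 0.98, camera adjusted p = 0.00337, and adjusted p = 0.411 with an estimated correlation); with total-count scaling 12 were higher and 5 lower, and with the GC trend removed 11 and 5. In the latter, KLF16 (0.30, SE 0.09) turned to -0.98 and passed as lower (edgeR adjusted p = 2.74e-08). KLF13 (0.54, SE 0.07) turned to -0.0025 without passing. The call of KLF16 was lost with total-count (adjusted p = 0.283) and upper-quartile scaling (0.0795). KLF3 (2.23, SE 0.04) and SP4 (2.07, SE 0.29) rose most, followed by KLF9 (1.96, SE 0.06) and KLF10 (1.68, SE 0.02). KLF11 (1.47, SE 0.13), KLF12 (1.38, SE 0.08), KLF8 (1.36, SE 0.18), SP1 (1.29, SE 0.06), SP3 (1.13, SE 0.04), SP2 (0.83, SE 0.10) and KLF7 (0.60, SE 0.11) rose as well. KLF5 (-2.22, SE 0.28) and KLF4 (-1.18, SE 0.07) fell.

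Extracellular matrix genes had 24 higher, 9 lower and 8 not passing of 41 (camera adjusted p = 0.732); with total-count scaling the split was 15 and 16, and with the GC trend removed 14 and 21. COL6A1 rose from 1538 ± 69.9 to 6562 ± 221 CPM (log2 fold change 2.09, SE 0.04, edgeR adjusted p = 3.31e-17) and COL11A1 rose (1.21, SE 0.07), while THBS1 (-1.40, SE 0.07) and the tenascin TNC (-1.02, SE 0.08) fell. TGF-beta and YAP response genes had 14 higher, 10 lower and 3 not passing of 27 (camera adjusted p = 0.666), and the split was 10 and 11 with total-count scaling and 9 and 13 with the GC trend removed. TGFB1 (1.61, SE 0.04) and AMOTL2 (1.58, SE 0.07) rose, and AMOTL1 fell (-1.33, SE 0.04). Fibroblast markers, many of which smooth muscle cells share, had 9 higher, 2 lower and 2 not passing of 13 (camera adjusted p = 0.104), and the split was 7 and 3 with total-count scaling and 6 and 4 with the GC trend removed. SCARA5 rose from 6.33 ± 4.60 to 143 ± 5.21 CPM (4.53, SE 0.44, and 5.16 without Ad-GFP library 4), IGFBP6 (3.30, SE 0.03) and MFAP5 (0.98, SE 0.13) rose, and PDGFRA fell (-0.67, SE 0.03).

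Markers of other cell types were mostly low. Only 4 leukocyte markers were high enough to test: CD14 and CD74 were higher and SRGN was lower (-0.36, SE 0.15). CD14 had 5 counts in Ad-GFP and 58 in Ad-KLF15. Its log2 fold change was 3.56, and 4.32 without Ad-GFP library 2. The rise of CD74 (0.59, SE 0.20) turned to -0.03 with the GC trend removed, and its call was lost with total-count scaling (adjusted p = 0.0863) and without Ad-KLF15 library 2 (0.0511). The call of SRGN was lost with DESeq2 (adjusted p = 0.0579), with the GC trend removed (0.125), against Ad-GFP libraries 1 and 2 alone (0.113), without Ad-GFP library 4 (0.0713) and without Ad-KLF15 library 1 (0.132) or 2 (0.0529). Of 6 tested epithelial markers, 4 were higher (camera adjusted p = 0.482): KRT19 went from 5.26 ± 1.66 to 18.9 ± 0.48 CPM, and KRT14, MUC5AC and CLDN4 stayed under 6 CPM. The calls of MUC5AC and CLDN4 were lost with the GC trend removed, and that of CLDN4 also with total-count (adjusted p = 0.0966) and upper-quartile scaling (0.0623), without Ad-GFP library 2 (0.0716) or 3 (0.0647) and without Ad-KLF15 library 1 (0.0617), 3 (0.0653) or 4 (0.0606). Of 6 endothelial markers, 2 were higher and 2 lower (camera adjusted p = 0.886). ROBO4 (4.50, SE 0.18) and EGFL7 (1.27, SE 0.18, but -0.04 with the GC trend removed) rose, TEK fell (-0.63, SE 0.16), and KDR had 106 counts in Ad-GFP and 3 in Ad-KLF15. Of 13 mitochondrially encoded mRNAs, 1 was higher and 8 lower (camera adjusted p = 0.285), and the split was 0 and 12 with total-count scaling, 1 and 12 with upper-quartile scaling and 1 and 6 with the GC trend removed. MT-ND2 (-0.55, SE 0.11), MT-ND6 (-0.37, SE 0.12) and MT-CO3 (-0.20, SE 0.05) fell, and MT-CO1 was higher (0.21, SE 0.03), but by 0.0047 and without passing under total-count scaling. In all, camera called 7 of 23 lists, 5 upward and 2 downward. Adjusted over the list alone, the counts of members were as given except for phospholipase C (13 higher), glycolysis (14 higher, 12 lower) and immediate-early genes (14 lower).

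**Figure D2:**
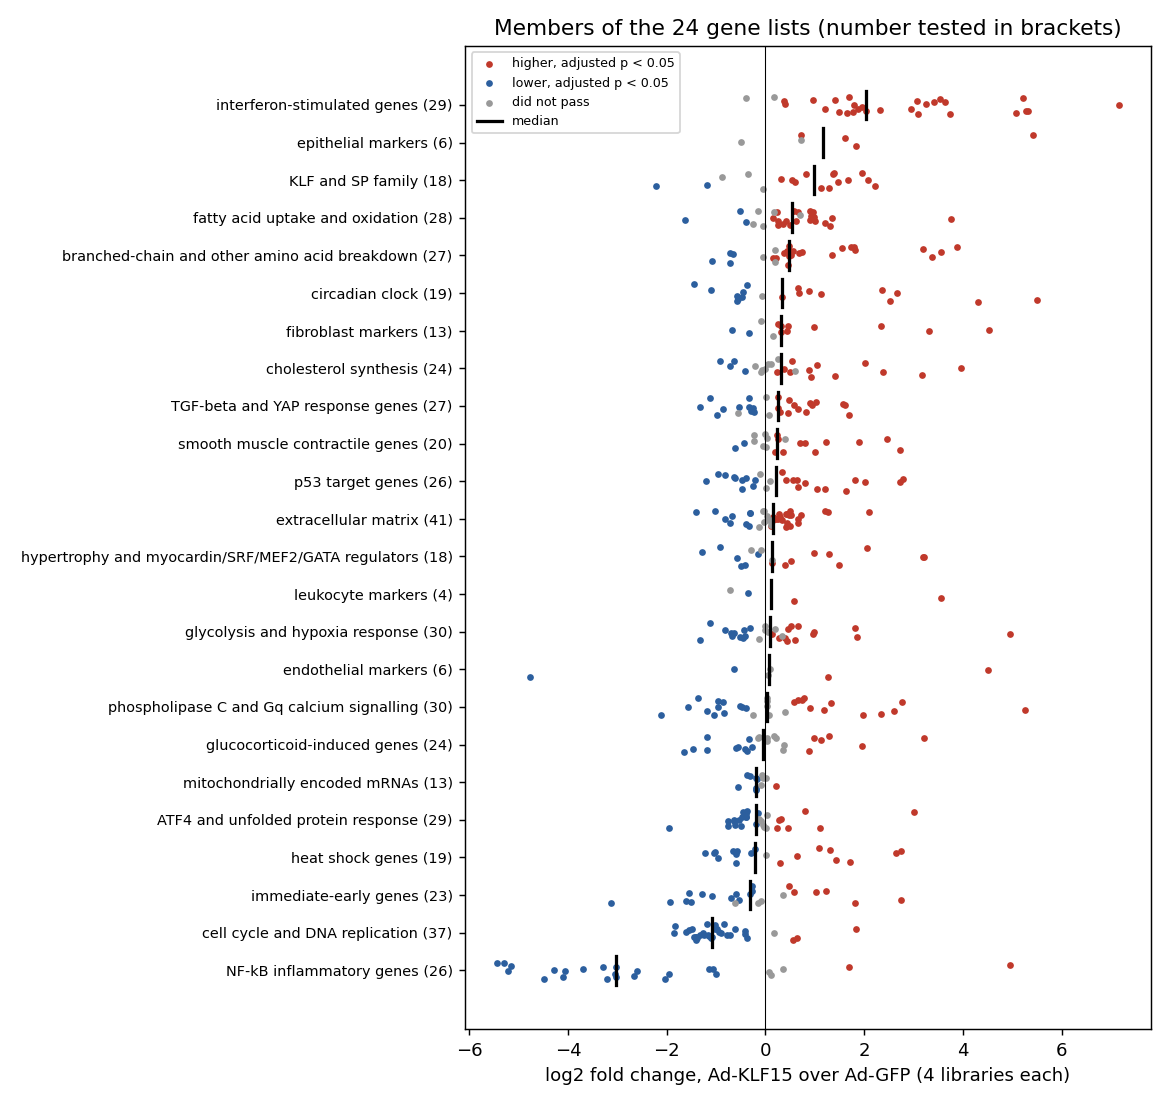
Log2 fold changes of Ad-KLF15 over Ad-GFP (horizontal axis) for the tested members of 24 gene lists (rows, with their number tested), 1 point per gene, coloured by whether it was higher, lower or did not pass, with a bar at the list median. Interferon-stimulated genes had the highest median, 2.03, and NF-kB inflammatory genes the lowest, -3.03, and both kept their direction under every scaling tried.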

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

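The beta-globin tests and the test of a GC bias differing between libraries were chosen only after the result was seen, as were the check of widened bins and the interval on tandem over divergent pairs. All 35 splits of the 8 libraries into 4 and 4 were refitted. Only 1 of 35, the real one, gave as many genes, with 11205 calls against 0 at the most in the others. Chance is argued against but not excluded, since this share, 0.0286, is the smallest these splits can give. Every other split mixes the groups, which widens its within-group spread, so the 0 calls give no measure of strength. The splits also cannot part KLF15 from anything else that follows the groups.

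In 16 of 256 groups of 4 libraries, 1 library stood far from the other 3, where chance gives about 12.8. Among controls, in CPM, these were KLF12 at 25.9 in library 1, EGFL7 at 3.45, GLUD1 at 176 and SH2D3C at 0.055 (its single count) in library 2, and NFATC4 at 26.5 in library 3. Ad-GFP library 4 stood apart for SCARA5 at 13.1, TEK at 12.1, GDF15 at 17.4 and DDIT3 at 16.2 CPM, the last being the lowest of 4. Among Ad-KLF15 libraries, KLF4 at 24.7 CPM was lowest in library 1, and COL9A3 at 41.9 and KLF9 at 81.4 CPM were lowest in library 4. In Ad-KLF15 library 2, CLDN4 was lowest at 3.68 CPM, and KLF7 at 64.9 and PLCB3 at 341 CPM were highest. DPYSL5 was highest in Ad-KLF15 library 3, at 1.16 CPM. Each of the 8 libraries stood apart for at least 1 gene.

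HBB, the adult beta-globin gene of red cells, was the second most abundant transcript of the controls, at 14033 ± 1135 CPM, and was at 4235 ± 197 CPM in Ad-KLF15 (SD, n = 4, log2 fold change -1.73, SE 0.07, edgeR adjusted p = 5.80e-15). HBD, the delta-globin gene, fell with it, from 49.8 ± 3.71 to 12.4 ± 1.60 CPM (log2 fold change -2.01, SE 0.10, edgeR adjusted p = 3.42e-12). HBD was not among the erythroid genes of the red cell test, and the origin of its reads was not tested. Red cells in the cultures are argued against by the other erythroid genes. ALAS2, SLC4A1, AHSP and CA1 together had 5.11 counts per 1000000 HBB counts in the controls, and HBA1 and HBA2 had 2 and 1 counts. A globin sequence carried by both vectors may be the source and stays open, since the lowest of the 8 transduced libraries had 4011 CPM and untransduced cells were not among the samples analysed here. A change of the cells' own HBB was not tested apart from it.

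GC-rich genes were higher in Ad-KLF15. The median log2 fold change was -0.23 in the lowest of 10 equal bins of transcript GC content and 0.62 in the highest. A bias differing from library to library is argued against, because the difference in this trend between groups was 18.8 times the largest SD within a group. A bias shared by all libraries of a group may contribute: 27.2% of genes in the highest bin lay below the median of all genes, past the 25% set beforehand as evidence against it. That bound does not decide, because the highest bin was also wider (interquartile range 1.84 against 0.92), and the 5 lower bins moved to its median and widened as much gave 30.4% to 31.4%. A response of GC-rich genes to KLF15, which binds GC-rich DNA, stays open as untested.

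Genes raised at least 4-fold lay next to one another: 196 neighbouring pairs among 12803 protein-coding genes, 2.47 times the 79.3 of 10000 shuffles (permutation p = 0.0001, the smallest they can give), and 1.76 times the number with shuffles matched on GC content. Reads of overlapping genes are argued against as the source of most of these pairs, as 17.3% of the pairs overlapped. They may account for some, since the share of overlaps among all neighbours was not computed. Transcription running on into the next gene could add to the same-strand pairs, at 2.86 times their expected number, but divergent pairs were also in excess, 2.15 times, and the ratio of these excesses, 1.33 (95% interval 0.94 to 1.88), does not part them. Shared regulation of neighbours stays open.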

How the results depend on the processing

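Total-count scaling, GC trend removal and the comparison with Ad-GFP libraries 1 and 2 alone were chosen after seeing the data. The total of called genes did not move by over 1.5 times: it ranged from 9634 at an adjusted p under 0.01 to 12391 without a filter, and from 10700 to 11220 with 1 library left out. KLF15 kept its direction and call wherever it had a value. Total-count scaling moved the median log2 fold change of all genes to -0.22, GC removal to -0.16 (4832 higher, 6731 lower) and upper-quartile scaling to -0.16 (4954 higher, 6655 lower), so directions of small changes depend on the scaling. With the GC trend removed, log2 fold changes turned for CD74 (-0.031), KLF16 (-0.98), KLF13 (-0.0025), EGFL7 (-0.043), PDLIM7 (-0.011) and FLNA (-0.066), and the cause was not tested. KLF16 then passed as lower (edgeR adjusted p = 2.74e-08), and the others did not pass. The removal takes out a response that follows GC content along with any bias, so these turns cannot tell them apart. Deviations of same-numbered libraries were hardly correlated over all genes (-0.008 to 0.059), and not every library correlated best with its own number. A pairing by number is not excluded, since library 4 had the highest share of reads in no annotated gene in each group (14.8% and 9.96%). The replicate block gave 5752 higher and 5361 lower genes and brought the contractile list past the threshold (camera adjusted p = 0.019) and no other. With an estimated correlation 6 of 7 called lists lost their call, with camera adjusted p of 0.361 for amino acid breakdown and cell cycle, 0.411 for fatty acids and the KLF and SP family, 0.587 for cholesterol and 0.794 for NF-kB. Without a filter, which adds silent genes to the background, camera also called contractile (0.000327), hypertrophy (0.00536), phospholipase C (0.0225), p53 (0.0270), clock (0.000599) and fibroblast (0.00136) lists. GC removal brought in the clock (0.0408) and immediate-early (0.0157) lists, and Ad-GFP libraries 1 and 2 alone the clock (0.0158) and fibroblast (0.00940) lists; the cause was not tested. With 1 library left out, adjusted p ran from 0.0228 to 0.0808 for contractile genes (passing without Ad-GFP 1, 0.0301, Ad-GFP 2, 0.0228, or Ad-GFP 4, 0.0418), from 0.0292 to 0.0995 for the clock and from 0.00834 to 0.128 for fibroblast markers, both passing only without Ad-GFP 4. Fry, which tests a list alone, passed all 7 lists that camera called, with NF-kB the weakest (fry adjusted p = 0.0175). It also passed contractile (0.000603), hypertrophy, phospholipase C and epithelial (each 1.07e-05), matrix (0.00507) and TGF-beta (0.000544) lists. The p53 (2.75e-06), clock (1.20e-05), heat shock (0.000102), mitochondrial (0.0277), endothelial (0.000387) and fibroblast (1.83e-06) lists passed fry as well. Glucocorticoid, ATF4, glycolysis and immediate-early lists did not pass it. CLDN4, SRGN, CD74, KLF16, MT-CO1 and MUC5AC each lost their call under at least 1 alternative. The calls of KLF13, EGFL7, PDLIM7 and FLNA were lost with the GC trend removed. Depth limits genes at a few counts, such as PRODH, which the count filter of the main test left out.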

Other observations

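Families of genes sharing a symbol were looked at after the data were seen, 22 in all, of which camera called 6, and none with an estimated correlation. Semaphorins, guidance proteins, had 13 higher and 4 lower of 20 tested (median log2 fold change 1.20, camera adjusted p = 0.00142, adjusted p = 0.394 with an estimated correlation). SEMA3B rose from 20.4 ± 0.58 to 353 ± 17.7 CPM and SEMA3F from 65.8 ± 7.06 to 327 ± 13.8 CPM, while SEMA3C fell by 1.01 on the log2 scale. Ephrins and Eph receptors had 9 higher and 3 lower of 18 (camera adjusted p = 0.0272, adjusted p = 0.616 with an estimated correlation), with EPHB3 up by 3.86 and EPHB2 at -1.30. Keratins had 7 higher and 1 lower of 9 (camera adjusted p = 0.00683, adjusted p = 0.394 with an estimated correlation), among them KRT8, from 14.3 ± 0.88 to 285 ± 12.6 CPM, and KRT18. Collagens had 20 higher and 5 lower of 33 (median 0.44, camera adjusted p = 0.0149, adjusted p = 0.748 with an estimated correlation), but their median turned to -0.29 with the GC trend removed.

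Mitochondrial ribosomal proteins had 49 lower and 11 higher of 76 (median -0.37, camera adjusted p = 0.00683, adjusted p = 0.616 with an estimated correlation), with MRPL3 at -1.07. Chemokines had 13 lower and 1 higher of 14 (median -3.12, camera adjusted p = 0.00683, adjusted p = 0.616 with an estimated correlation), many of them members of the NF-kB list too. Part of the fall rests on Ad-GFP library 4, without which the log2 fold change went from -5.45 to -4.47 for CXCL3, from -5.15 to -4.13 for CXCL8, from -4.49 to -3.71 for CCL20 and from -4.27 to -3.24 for CXCL1. CXCL12 fell by 1.14 on the log2 scale and CXCL16 was higher by 0.68. Metallothioneins had 6 lower of 7 (median -1.19), but the family did not pass (camera adjusted p = 0.103). Of 12 genes of HLA class I and antigen processing, 8 were higher and 1 lower (camera adjusted p = 0.0917), with TAP1 at 1.68 and TAPBP at 1.90, while HLA-B and HLA-C, higher by 0.34 and 0.44, turned to -0.29 and -0.47 with the GC trend removed. HBA1 and HBA2, the alpha-globin genes, went from 2 and 1 counts in Ad-GFP to 137 and 159 in Ad-KLF15.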
